A study of Arabidopsis thaliana with 8 samples.

How the data were processed

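The samples were roots of Arabidopsis thaliana, wild type (WT) and hy5 mutant, kept in medium with or without the cytokinin benzyladenine (BA), with 2 libraries in each of 4 groups (WT Control, WT BA, hy5 Control and hy5 BA). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, frozen tissue was extracted with CTAB, polyadenylated RNA was selected with oligo-dT and fragmented by heat, cDNA was primed at random, and Kapa TruSeq adapters were ligated. The strand setting of the libraries is not given in the sources used here.

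Each library had 1 deposited table of transcripts with their length, effective length, TPM and estimated count. The estimated counts are those the authors obtained with Salmon, and the submitters' processing notes name TAIR10 as the build; the version of Salmon and its options are not given in the sources used here. Per the file headers, the deposited TPM values are scaled by the authors, and they were used here only as a second scale for HY5. The deposited effective length was the transcript length less 249 bases for most transcripts, and it was used only in 1 alternative. In hy5 Control 1 and hy5 BA 2, 20.1% and 22.4% of the transcripts had an estimated count within 0.001 of a whole number without being whole, against 1.17 to 1.33% in the other libraries. Counts of calls were therefore also made without both, an alternative chosen after seeing the data, as was the test of the gene lists with library size only.

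The estimated counts of 48332 transcripts were summed to 27628 genes by the locus code before the dot and rounded to whole numbers. Gene symbols, coordinates and strands came from a reference annotation of the build TAIR10.1, which held 27420 of the genes and a symbol for 10361 of them; 208 genes were not in it. The transcript lengths in the deposited tables equalled those of the annotation for 99.59% of transcripts. Totals per library lay between 29928501 and 35289411 estimated counts. Both libraries of every group differed by more than sampling noise: the chi-square per gene between them was 8.24 in WT Control, 7.16 in WT BA, 3.86 in hy5 Control and 5.51 in hy5 BA, where sampling noise alone gives about 1. No library was therefore counted as a copy of another.

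Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, about 0.307 CPM, counts scaled to library size), which left 22682 genes and removed 4946. Library sizes were scaled with TMM, and 1 robust quasi-likelihood model with 4 group means was fitted over all 8 libraries, with 4 residual and a median of 11.9 prior degrees of freedom; the common biological coefficient of variation was 0.0596. The contrasts were the BA response in WT, the BA response in hy5, the hy5 effect in control medium, the hy5 effect with BA, the genotype by BA interaction (the BA response in hy5 less that in WT) and the BA response and hy5 effect averaged over the other factor. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. All tests were two-sided.

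A total of 26 gene lists, 4 of them markers of cell types, together with the designs, the alternatives and the rule for named genes, were fixed before the data were examined. They covered cytokinin signalling, metabolism and response (6 lists), HY5 and light signalling, flavonoid synthesis, photosynthesis, nitrate, phosphate and sulfate, iron, auxin (2 lists), ethylene, root hairs, Casparian strip and suberin, cell cycle, circadian clock, wounding and jasmonate, hypoxia, heat shock, and markers of shoot, root meristem and cap, xylem and phloem. Of 387 list members, 386 were in the tables; ARR2 was not analysed here. Lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists within each contrast, and again with the correlation estimated from the data. A call with the preset correlation alone rests on that value.

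The genes named in each comparison were the 6 rising and 6 falling genes with the largest fold among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries compared (this last condition was not set for the interaction), HY5 and HYH, and up to 4 called members of each list with the smallest p, or the 2 members with the smallest p where a passing list had no called member. From these, the text gives mainly genes that were called in every run that left out 1 library. A gene without a symbol is given by its locus code.

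The steps were tested on simulated data made from the libraries' own means and sizes, with 200 of 22682 genes changed (67, 67 and 66 genes at 1.5-, 2- and 4-fold). At 1.5-, 2- and 4-fold the fit recovered 68.7, 89.6 and 100% of them for the BA response in WT, 61.2, 82.1 and 97.0% for the BA response in hy5, 77.6, 85.1 and 98.5% for the hy5 effect in control medium, 79.1, 88.1 and 95.5% for the hy5 effect with BA, 37.3, 71.6 and 84.8% for the interaction, and 89.6, 94.0 and 98.5% for the averaged BA response. The false share of the calls was 5.7, 9.1, 10.8, 9.8, 8.5 and 10.9% in the same order, above the nominal 5% in each. In the simulated BA response in WT, where the type-A list was changed as well, that list had an adjusted p of 6.31e-77 with camera and 0 other lists passed. Genes were drawn independently and in 1 draw, so this does not show how often lists of correlated genes pass falsely. In the same simulated data DESeq2 1.42.0 recovered 81.5% and limma-voom 84% of the changed genes, with 15 false calls each.

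The alternatives were RLE size factors, library size only, no filter and a stricter filter (CPM of at least 1 and 10 counts in at least 2 libraries), DESeq2, limma-voom, the replicate number as a block, an offset for effective length, only the 4 libraries compared, no robust step, genes of the organelle genomes left out, an adjusted p under 0.01, a fold of at least 2, and leaving out each library in turn. A run that leaves 1 library in a group assumes that it varies like the other groups. Transcripts of the named genes were aligned to all transcripts of the annotation with blastn 2.17.0: 10 of 197 had a stretch of at least 95% identity over at least 50% of their length in another gene, and 46 overlapped another gene in position. How Salmon divided reads between such genes, and whether it used strand, is not given in the sources used here, so their values are uncertain. Figures were drawn with matplotlib 3.10.9 in python 3.11.15 (numpy 2.4.6, pandas 2.3.3).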

Results

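Gene expression was measured in Arabidopsis roots to see what a cytokinin changes in wild type and in plants without HY5, a bZIP transcription factor that promotes light responses. Plants grew upright for 1 week on 0.5x Murashige and Skoog medium, the root was cut from the shoot, and roots were put in liquid medium with or without 0.1 uM benzyladenine (BA), a cytokinin. The length of the treatment and the hy5 allele are not given in the sources used here. Polyadenylated RNA was sequenced from 8 libraries, 2 for each of WT Control, WT BA, hy5 Control and hy5 BA. Their totals were 33875892 and 30595295 estimated counts in WT Control, 29928501 and 31545336 in WT BA, 33990803 and 33582201 in hy5 Control, and 35289411 and 31458552 in hy5 BA. No single gene took more than 0.56% of a library. Along the first principal component of the 500 most variable genes, with 71.5% of the variance, the genotypes lay apart, and along the second, with 12%, the libraries with and without BA. Fold changes below are log2 values from edgeR ± SE, with n = 2 libraries per group and Benjamini-Hochberg adjusted p. The SE of a fold was derived as its absolute value divided by the square root of the quasi-likelihood F. It therefore rests on a spread pooled over all groups. The labels do not say that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. Genes named as changed kept that call in each run that left out 1 library, unless the loss is given. The number of called members of a list was less steady, and for lists that passed, counts of 2 or more given below that moved by more than 1.5 times without 1 library are given with their value there. The values of ARR6, ARR9, CKX5, CKX6, IAA3, IAA5, HRE1, PSBR, TCH3, SPA3, SPA4, TT4, BBX20, ASN1, JAZ10, XCP1, CESA4, CESA7, CESA8, EXPA7, EXPA18 and AT1G34047, whose positions overlap another gene, and of PHT1;1, F3H, PRR9 and AT5G33355, which share sequence with another gene, are uncertain to that extent.

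HY5 itself (AT5G11260, chromosome 5, 3593335 to 3595073, minus strand, TAIR10.1) followed the genotype labels in all 8 libraries. It stood at 31.7 ± 0.96 CPM in WT Control and 31.2 ± 0.23 CPM in WT BA, and at 0.88 ± 0.07 CPM in hy5 Control and 1.48 ± 0.70 CPM in hy5 BA (mean ± SD, n = 2). The fold between genotypes was -5.17 ± 0.18 in control medium (adjusted p = 3.67e-11) and -4.37 ± 0.16 with BA (adjusted p = 9.94e-11). Its close relative HYH (AT3G17609, chromosome 3, 6023844 to 6024710, plus strand) was also lower in hy5, at -3.01 ± 0.16 and -2.73 ± 0.15. Neither gene passed the test for BA in either genotype. For HY5 the fold was -0.03 ± 0.11 in WT (adjusted p = 0.91) and 0.77 ± 0.28 in hy5 (adjusted p = 0.0997), where the higher value came from hy5 BA 1, with 70 counts against 32 in hy5 BA 2.

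**Figure D1:**
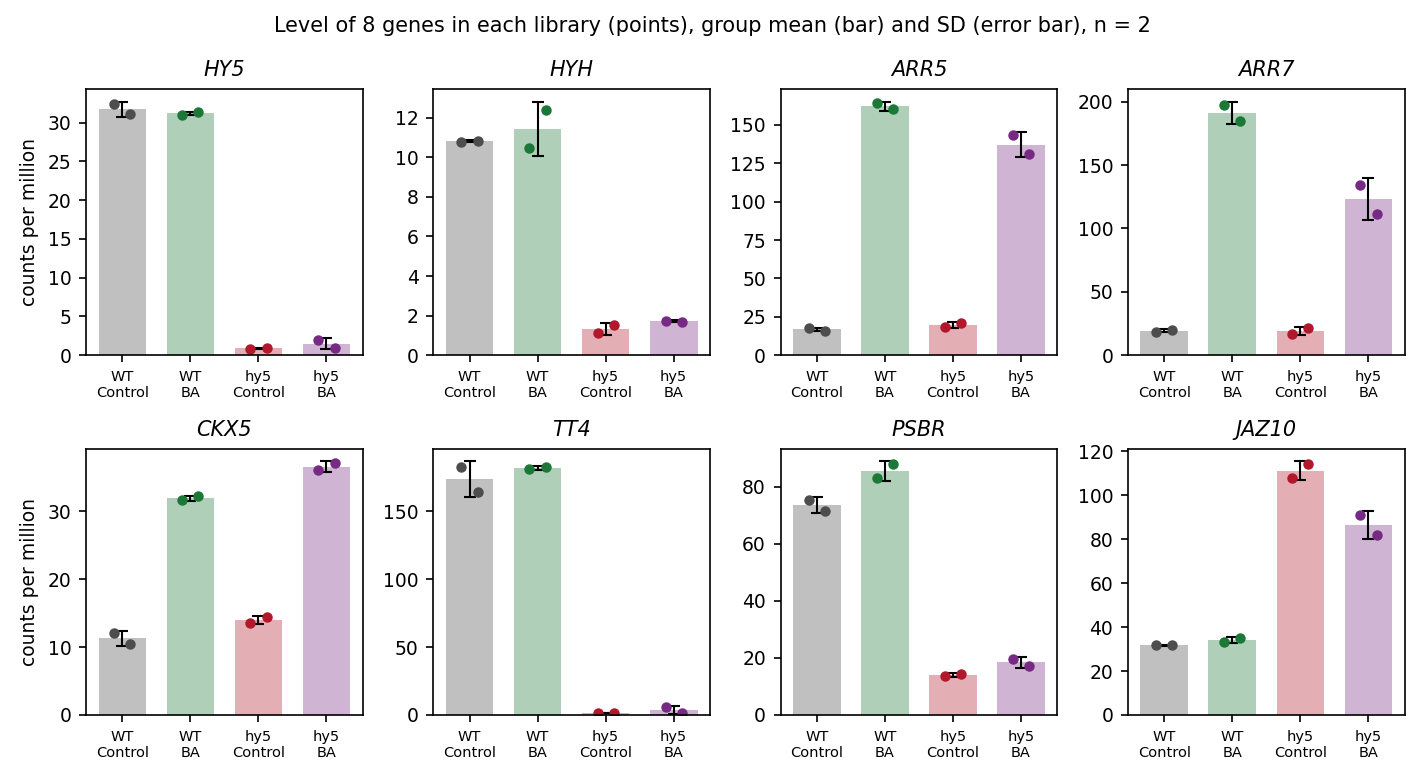
Expression of 8 genes in CPM (vertical axes, starting at 0) in the 8 libraries (points), with the mean of each group (bars) and its SD (n = 2). HY5 was near 31 CPM in both WT groups and near 1 CPM in both hy5 groups, ARR5 rose with BA from 16.8 to 162 CPM in WT and from 19.6 to 137 CPM in hy5, and TT4 was at 174 CPM in WT Control and 1.14 CPM in hy5 Control.

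In WT roots BA raised the type-A response regulators, genes of cytokinin breakdown and other genes known to be induced by cytokinin. ARR5 (chromosome 3, 17758427 to 17760950), a type-A response regulator of cytokinin signalling, rose from 16.8 ± 1.0 to 162 ± 2.9 CPM, a fold of 3.27 ± 0.09 (adjusted p = 1.16e-12). ARR7 rose by 3.31 ± 0.12 and its neighbour AT1G19040 (chromosome 1, 6576077 to 6577413, next to ARR7 at 6577833 to 6579314) by 4.24 ± 0.14, the largest rise among the genes named by rule. CKX5, a cytokinin oxidase that degrades the hormone, rose from 11.3 to 31.9 CPM (adjusted p = 1.1e-08). Falls were smaller, such as those of AT2G41810 (-1.72 ± 0.21) and WAG1 (-1.31 ± 0.19), which codes for a protein kinase of the auxin transport pathway. Of 22682 genes tested, 1861 were called, 879 higher and 982 lower with BA, and of the 220 changed at least 2-fold 186 were higher and 34 lower.

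The type-A response regulators, which damp the cytokinin signal, rose as a whole: 10 of 10 rose, also 10 when adjusted over the list alone, with a median fold of 1.97 (camera adjusted p = 3.05e-125, and adjusted p = 0.00187 with an estimated correlation). ARR6 rose by 2.84 ± 0.10, ARR4 by 2.46 ± 0.07 and ARR9 by 1.70 ± 0.09. Of 9 genes of cytokinin breakdown and conjugation, 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.41e-20, and adjusted p = 0.00636 with an estimated correlation). Called members included the oxidases CKX3 (2.24 ± 0.21) and CKX6 (2.05 ± 0.14) and the glucosyltransferase UGT85A1 (1.27 ± 0.12). Of 11 cytokinin response factors and other genes known to be induced by the hormone, 7 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 2.29e-19, and adjusted p = 0.00636 with an estimated correlation). Examples were LBD3 (2.95 ± 0.14), IAA3 (1.18 ± 0.09) and CRF6 (0.99 ± 0.11). The 14 genes of cytokinin synthesis and activation split, with 2 higher and 4 lower by either adjustment (adjusted p = 0.913). CYP735A2, which makes trans-zeatin, rose by 1.92 ± 0.10 and AT2G35990 by 1.56 ± 0.19. The isopentenyltransferase IPT5 fell by 0.93 ± 0.11. Of 9 receptors and phosphotransfer proteins 3 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.305). The receptor WOL (also called AHK4) rose by 1.02 ± 0.07 and the receptor AHK2 fell by 0.54 ± 0.09. Of 6 type-B regulators, the transcription factors of the pathway, 2 rose and 3 fell by either adjustment (adjusted p = 0.975). ARR12 was at 0.67 ± 0.07 and ARR11 at -0.61 ± 0.10.

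Root hair genes and endodermal barrier genes also passed in WT, with less support. Of 9 root hair genes 4 rose and 0 fell (4 and 2 adjusted over the list alone; adjusted p = 0.0227, but adjusted p = 0.86 with an estimated correlation). Among these were the hair regulators RSL4 (1.01 ± 0.13) and RSL1 (1.07 ± 0.15), and 2 members were called without WT Control 1, without WT Control 2 and without WT BA 2. Of 20 Casparian strip and suberin genes 3 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0227, but adjusted p = 0.875 with an estimated correlation). One of them was the fatty acyl reductase FAR5 (0.49 ± 0.09). Both lists lost their call without WT Control 2 (adjusted p = 0.166 for root hairs and 0.331 for the barrier) and without WT BA 2 (0.312 and 0.273). Among 15 ethylene genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.716). The ACC synthases ACS5 and ACS2, which start ethylene synthesis, rose by 2.27 ± 0.15 and 1.23 ± 0.10, and the response factor ERF1 fell by 0.80 ± 0.11. The 18 auxin-induced genes went both ways, 4 up and 4 down (6 and 5 adjusted over the list alone; median 0.16, mean -0.02, adjusted p = 0.716). IAA5 was at 2.31 ± 0.21 and GH3.1 at -0.95 ± 0.12. Of 17 nitrate and ammonium genes 4 rose and 1 fell (6 and 3 adjusted over the list alone; adjusted p = 0.305). The high-affinity nitrate transporter NRT2.4 was at 1.91 ± 0.30, a call that DESeq2 did not make. The 26 light signalling genes had 4 up and 2 down by either adjustment (adjusted p = 0.662), such as BBX20 (0.95 ± 0.13), and 10 hypoxia genes had 1 up and 2 down (2 and 3 adjusted over the list alone; median 0.12 and mean 0.04 against a downward test, adjusted p = 0.949), such as HRE1 (-0.60 ± 0.09).

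The remaining lists did not pass in WT. None of the members was called among 26 cell cycle genes (adjusted p = 0.448), 47 photosynthesis genes (0.716), 8 phosphate and sulfate genes (0.975), 5 heat shock genes (0.773), 7 shoot markers (0.949) and 6 xylem markers (0.448), and adjusted over the list alone only 3 xylem markers were lower. The counts of higher and lower members were 1 and 0 of 20 iron genes (adjusted p = 0.305), 1 and 0 of 15 flavonoid genes (0.448), 1 and 1 of 19 clock genes (0.949), 0 and 1 of 11 wounding genes (0.716), 1 and 1 of 13 auxin transport genes (0.975), 0 and 1 of 8 root meristem and cap markers (0.949) and 0 and 1 of 3 phloem markers (0.618). Adjusted over the list alone, 2 auxin transport genes were lower and the other counts stayed as they were. The median, mean and test differed in sign in several lists that did not pass: auxin transport (0.03 and 0.01, test down), phosphate and sulfate (0.02 and 0.04, down), receptors (-0.02 and -0.01, up), type-B regulators (-0.08 and -0.05, up), ethylene (-0.01 and 0.11, up) and cytokinin synthesis (-0.01 and 0.045, up). The number of calls fell without WT Control 1 and without WT BA 2, changed little without WT BA 1 and rose without WT Control 2. A run that leaves 1 library in a group also has less power. The falls therefore do not show that the calls rested on those libraries.

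In hy5 roots BA also raised the cytokinin markers. ARR5 rose from 19.6 ± 2.0 to 137 ± 8.4 CPM, a fold of 2.81 ± 0.09 (adjusted p = 9.47e-12), ARR7 rose by 2.70 ± 0.12 and AT1G19040 by 4.29 ± 0.15. Among the largest falls were AT2G41810 (-2.03 ± 0.20), AT1G64380 (-1.89 ± 0.18) and RTFL5 (-1.83 ± 0.19), which codes for a small peptide of a family that restrains cell proliferation. The test called 2523 genes, 706 higher and 1817 lower, of which 140 and 100 changed at least 2-fold. Both genotypes called 347 genes higher, where independent lists would share 27.4, and 540 lower, where they would share 78.7. A further 6 genes were called in opposite directions. Over all genes the folds had r = 0.302 and rho = 0.324, a description across genes that share no library.

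Of 10 type-A regulators 9 rose (10 adjusted over the list alone; median 1.60, adjusted p = 4.25e-91, and adjusted p = 0.00452 with an estimated correlation). ARR6 was at 2.59 ± 0.10 and ARR4 at 1.87 ± 0.07. Of 9 breakdown and conjugation genes 4 rose (5 adjusted over the list alone; adjusted p = 4.23e-11, and adjusted p = 0.0251 with an estimated correlation). CKX5 was at 1.38 ± 0.08 and CKX6 at 1.52 ± 0.14. Of 11 response factors and induced genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 1.16e-05, but adjusted p = 0.079 with an estimated correlation). LBD3 was at 2.30 ± 0.15 and IAA3 at 0.64 ± 0.09. As in WT, CYP735A2 rose (1.84 ± 0.10) and IPT5 fell (-0.73 ± 0.12). LOG1, which releases active cytokinin, was at -0.75 ± 0.10, and its fall in WT (-0.51 ± 0.10) was not called without WT Control 1 (adjusted p = 0.0577) or without WT BA 2 (0.076). Of the 14 synthesis genes 2 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.878). The auxin-induced genes LBD29 and LBD16, which act in lateral root initiation, fell by 1.17 ± 0.13 and 0.98 ± 0.13. IAA5 rose as well, and of the 18 genes 3 were higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.273).

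Several stress and nutrient lists passed in hy5, none of them with an estimated correlation. The BA response in hy5 and the hy5 effect in control medium below share the hy5 Control libraries. Opposite directions of a list in these comparisons may come in part from those libraries. Of 11 wounding and jasmonate genes 6 fell (8 adjusted over the list alone; adjusted p = 2.94e-05, but adjusted p = 0.61 with an estimated correlation), and 3 without hy5 Control 1, 2 without hy5 Control 2 and 1 without hy5 BA 2. The calmodulin-like touch gene TCH3 was at -0.59 ± 0.09. JAZ10, a repressor of jasmonate signalling, was at -0.36 ± 0.07, a call lost without hy5 Control 2 (adjusted p = 0.0593) and without hy5 BA 2 (0.0709). Without hy5 Control 1 and hy5 BA 2 together the adjusted p was 0.139 for JAZ10. Of 8 phosphate and sulfate genes 2 fell (4 adjusted over the list alone; adjusted p = 0.00595, but adjusted p = 0.269 with an estimated correlation), with 1 called without hy5 Control 1 or 2 and 5 without WT Control 1, WT Control 2 or WT BA 1. The phosphate transporter PHT1;1 was at -0.44 ± 0.07. Of 10 hypoxia genes 1 rose and 4 fell by either adjustment (adjusted p = 0.0498, but adjusted p = 0.635 with an estimated correlation). HRE2 was at -0.87 ± 0.12. Without hy5 Control 2 and without hy5 BA 2, 2 members fell. This list was not called without hy5 Control 2 (adjusted p = 0.34), without hy5 BA 2 (0.263) or with RLE scaling (0.0571). Of 47 photosynthesis genes 6 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.46, adjusted p = 2.31e-08, but adjusted p = 0.61 with an estimated correlation). The number that rose was 1 without hy5 Control 1, 18 without hy5 Control 2, 2 without hy5 BA 1, 1 without hy5 BA 2 and 11 without WT Control 1 or 2. Of these genes PSBR, of photosystem II, rose from 14.0 ± 0.55 to 18.5 ± 1.9 CPM (0.40 ± 0.09), a call lost without hy5 Control 1 (adjusted p = 0.0964) and without hy5 BA 1 (0.134). Of 6 xylem markers 4 fell (5 adjusted over the list alone; median -0.36, adjusted p = 0.00612, but adjusted p = 0.61 with an estimated correlation). All 4, CESA4, CESA7, CESA8 and XCP1, lost their call without hy5 Control 2 (adjusted p from 0.0852 to 0.201), without hy5 BA 1 (0.0515 to 0.108) and without hy5 BA 2 (0.09 to 0.261), and without hy5 Control 1 only CESA4 was called. Summed, the 6 markers stood at 572 and 579 CPM in hy5 Control and 469 and 452 CPM in hy5 BA. Shoot markers had 0 calls of 7 (median 0.02 and mean -0.03, adjusted p = 0.886).

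The split between higher and lower calls in hy5 turned with 1 of the other scalings: with library size only, 1712 genes were higher and 1285 lower. That scaling moved the median fold of all genes by 0.0826. With RLE, 610 genes were higher and 1891 lower. The number of calls fell to 1355 without hy5 Control 1 (281 higher and 1074 lower), 1191 without hy5 Control 2 (331 and 860) and 1088 without hy5 BA 2 (316 and 772). Higher calls numbered 440 without hy5 BA 1. The total was 585 (167 and 418) without hy5 Control 1 and hy5 BA 2 together, the libraries whose estimated counts lay near whole numbers more often.

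**Figure D2:**
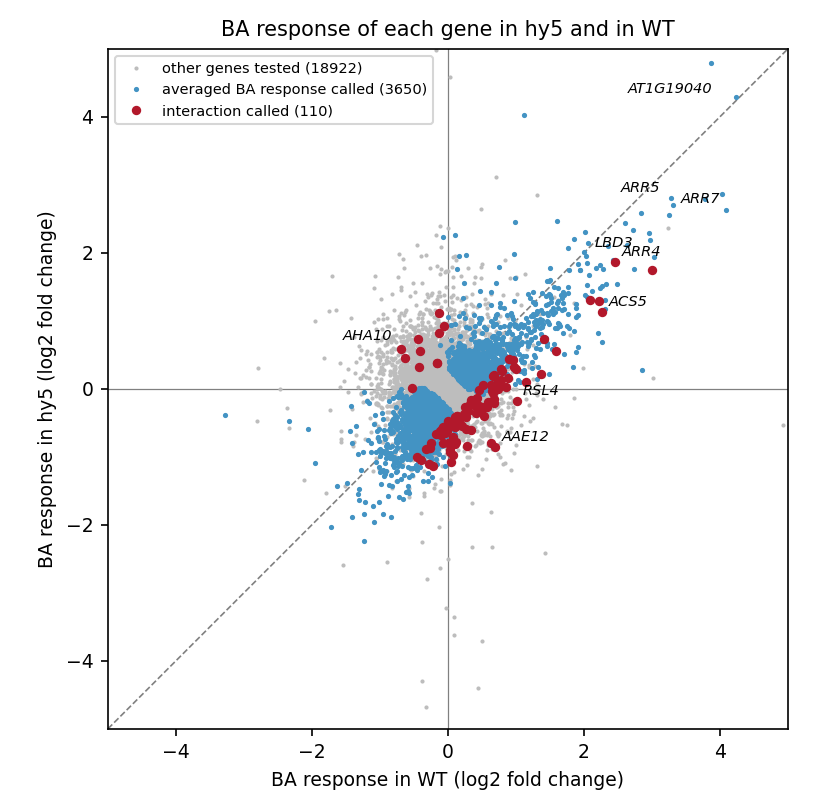
BA response of each gene tested, as log2 fold change in WT (horizontal axis) and in hy5 (vertical axis), with 18922 genes in grey, 3650 called for the averaged BA response in blue and 110 called for the interaction in red; 13 genes lie outside the axes and the dashed line marks equal responses. ARR5 (3.27 and 2.81) and ARR7 (3.31 and 2.70) lie below the line, as do 99 of the 110 interaction genes.

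The interaction asked which genes answered BA differently in hy5 and WT. It called 110 genes, 99 with a more negative response in hy5 and 11 with a more positive one. Among the former were AT4G22620 (-1.14 ± 0.15, adjusted p = 0.00516), the type-A regulator ARR4 (-0.59 ± 0.10, adjusted p = 0.0211), the ACC synthase ACS5 (-1.15 ± 0.20, adjusted p = 0.0211) and the root hair regulator RSL4 (-1.19 ± 0.18, adjusted p = 0.0146). ARR4 rose in both genotypes, by 2.46 in WT and 1.87 in hy5, and ACS5 by 2.27 and 1.12. Of the 99 genes, BA raised 51 and lowered 6 in WT and raised 13 and lowered 53 in hy5, with median folds of 0.33 and -0.38. Independent lists would share 3.8 and 4.3 genes in WT and 3.1 and 7.9 in hy5. The 11 positive genes had medians of -0.41 in WT and 0.56 in hy5, and included 2 genes of the chloroplast genome, ATCG00680 (1.17 ± 0.22) and ATCG00020 (0.98 ± 0.18). Of the 99, 84 were higher in hy5 Control than in WT Control, where independent lists would share 13.5, and all 11 positive ones were lower, where 1.3 would be shared. The interaction uses the same libraries as the BA responses and the hy5 effect, so the opposite medians follow in part from how these genes were selected. The r of the interaction was -0.574 with BA in WT, 0.607 with BA in hy5 and -0.478 with the hy5 effect in control medium. Groups simulated without effects gave -0.717, 0.708 and -0.706, values from noise alone that are not comparable in size with the observed r. The covariances were -0.09, 0.098 and -0.125 against -0.048, 0.047 and -0.047 simulated. Part of each covariance, and of the overlaps above, may therefore come from shared libraries.

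A total of 11 gene lists passed for the interaction, none of them with an estimated correlation. The type-A regulators were lower by a median of 0.41 on the log2 scale, with 1 of 10 called (5 adjusted over the list alone; adjusted p = 3e-04, but adjusted p = 0.317 with an estimated correlation). The response factors and induced genes had 1 of 11 called, ST4B at -0.73 ± 0.13 (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.000264, but adjusted p = 0.307 with an estimated correlation). Their median was -0.35 and their mean 0.08, with GATA21 at 0 in hy5 Control. Without WT Control 1 and without hy5 BA 1, 2 members of each of these lists were called. Photosynthesis genes had a median of 0.48 with 0 of 47 called by either adjustment, though 4 rose without hy5 Control 2 (adjusted p = 1.1e-08, but adjusted p = 0.5 with an estimated correlation). The number of calls changed with most libraries left out, from 110 to 331 without WT Control 1, 14 without WT BA 1, 17 without WT BA 2, 7 without hy5 Control 1, 23 without hy5 Control 2, 271 without hy5 BA 1 and 6 without hy5 BA 2. Without WT Control 2 it was 79, with 23 positive and 56 negative. Without hy5 Control 2, 12 of the 23 were positive and 11 negative, so the negative majority was not seen among the calls of that run. Of the genes named, AT4G22620 alone was called in each of these runs. ARR4, ACS5 and RSL4 all lost their call without WT BA 2 (adjusted p = 0.064, 0.0666 and 0.064), without hy5 Control 1 (0.098, 0.131 and 0.0917) and without hy5 BA 2 (0.143, 0.131 and 0.0909). ARR4 and ACS5 also lost it without WT BA 1 (0.0599 and 0.0635), and ARR4 without hy5 Control 2 (0.137). ST4B kept its call without WT Control 1 and without hy5 BA 1 and lost it in the other 6 runs (adjusted p from 0.053 to 0.143), and the chloroplast genes ATCG00680 and ATCG00020 kept theirs only without WT Control 1 or 2 (0.0524 to 0.184 in the others). Without hy5 Control 1 and hy5 BA 2 together, the total was 6, and AT4G22620 (adjusted p = 0.0869), ARR4 (0.336), ACS5 (0.436) and RSL4 (0.223) were not called. With library size only, which moved the median interaction of all genes by 0.106, 22 genes were positive and 33 negative, and ARR4 had an adjusted p of 0.0501.

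To compare the size of the response, genes were taken from the BA response averaged over genotypes, which favours neither genotype only where both vary alike. The chi-square per gene between libraries was higher in the WT groups. The averaged response called 3728 genes, 1465 higher and 2263 lower (2219 and 1896 with library size only). The rising genes had a median fold of 0.355 in WT and 0.292 in hy5, and 66.5% of them changed more in WT. The jackknife SE of that share over the 8 libraries was 13.9. This jackknife and those below treat the 8 libraries as 1 sample, though they are 4 groups of 2, so their SEs are rough. Here the genes were also selected anew in each run. The falling genes had medians of -0.274 and -0.372, and 32.1% changed more in WT (SE 20.7). The median interaction was -0.0811 (SE 0.0808) for rising and -0.109 (SE 0.148) for falling genes. By these rough SEs neither lay clear of 0 by more than about its error. Runs that left out 1 library gave -0.183 to -0.0966 for rising and -0.212 to -0.0363 for falling genes, all negative. Those for rising genes all lay beyond -0.0811, so the SE does not measure the error of that value well. With library size only, 41.9% of the rising genes changed more in WT and their median interaction was 0.0391. Across genes, which are not replicates, the folds in both genotypes had r = 0.697 among rising and 0.401 among falling genes. The number called was 2400 without hy5 Control 2 (840 higher), and higher calls numbered 910 without hy5 Control 1 and 839 without hy5 BA 1.

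The hy5 effect in control medium gave more calls than BA, with flavonoid and photosynthesis genes low and jasmonate genes high. With an estimated correlation the flavonoid list passed, and the photosynthesis and jasmonate lists did not (adjusted p = 0.11 each). TT4 (AT5G13930, chromosome 5, 4488476 to 4490264), the chalcone synthase that starts flavonoid synthesis, stood at 174 ± 13 CPM in WT Control and 1.14 ± 0.06 CPM in hy5 Control, a fold of -7.25 ± 0.52 (adjusted p = 0.000799). PSBR fell from 73.6 ± 2.7 to 14.0 ± 0.55 CPM (-2.39 ± 0.08, adjusted p = 8.44e-12). JAZ10 (chromosome 5, 4218786 to 4221077) rose from 31.9 ± 0.23 to 111 ± 4.3 CPM (adjusted p = 4.86e-11). The largest rises named by rule were in AT5G33355 (6.05 ± 0.27), AT1G34047 (5.11 ± 0.30) and AT2G36255 (4.75 ± 0.19), and the first of these shares sequence with AT3G59930. In control medium 5696 genes were called, 3103 higher and 2593 lower in hy5, of which 591 and 606 changed at least 2-fold.

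Of 15 flavonoid genes 9 fell (10 adjusted over the list alone; median -1.60, adjusted p = 5.76e-34, and adjusted p = 0.00492 with an estimated correlation). They included flavonol synthase FLS1 (-6.19 ± 0.19), chalcone isomerase TT5 (-3.76 ± 0.16) and F3H (-6.44 ± 0.28), which shares sequence with an antisense gene, AT3G51238, that was not tested. Of 26 HY5 and light signalling genes 17 fell and 3 rose (18 and 3 adjusted over the list alone; adjusted p = 1.3e-19, and adjusted p = 0.0121 with an estimated correlation), with SPA3 (-2.16 ± 0.13) and SPA4 (-2.29 ± 0.15), partners of the ubiquitin ligase COP1, beside HY5 and HYH. HY5 is the mutated gene, so its part in this test was fixed by the genotype, and the list was not tested without HY5. The number that rose was 1 without WT Control 2 and 0 without hy5 Control 1 or 2. Of 47 photosynthesis genes 35 fell and 0 rose (36 and 0 adjusted over the list alone; median -1.84, adjusted p = 1.73e-44, but adjusted p = 0.11 with an estimated correlation), and without hy5 Control 1 there were 2 that rose. Members that fell included GUN5, a subunit of magnesium chelatase (-3.51 ± 0.12), PSAF (-4.03 ± 0.19) and PSBO1 (-2.60 ± 0.10). The list summed to between 748 and 888 CPM in the WT libraries and between 249 and 332 CPM in the hy5 libraries, while the 7 shoot markers summed to between 73.3 and 87.7 CPM and did not pass (2 rose by either adjustment; adjusted p = 0.673). All 11 wounding and jasmonate genes rose (11 adjusted over the list alone; adjusted p = 4.85e-28, but adjusted p = 0.11 with an estimated correlation). AOS, an enzyme of jasmonate synthesis, was at 1.58 ± 0.09 and JAZ8 at 1.49 ± 0.10. The xylem markers also stood higher, and 5 of 6 rose by either adjustment (adjusted p = 0.0129, but adjusted p = 0.543 with an estimated correlation, and adjusted p = 0.0889 without WT Control 2). Without WT Control 2, hy5 Control 1 and hy5 Control 2 in turn, 2, 3 and 2 of them rose. The protease XCP1 was at 0.72 ± 0.09.

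Clock and hypoxia genes passed in control medium with less support. Of 19 clock genes 6 rose and 7 fell (6 and 8 adjusted over the list alone; adjusted p = 0.0096, but adjusted p = 0.543 with an estimated correlation), with the morning genes LHY (-2.15 ± 0.08), CCA1 (-1.39 ± 0.08) and PRR9 (-1.18 ± 0.10) all lower. Of 10 hypoxia genes 8 fell by either adjustment (adjusted p = 0.0113, but adjusted p = 0.543 with an estimated correlation). An example was the sucrose synthase SUS4 (-0.71 ± 0.08). Neither list was called without hy5 Control 1 (adjusted p = 0.0573 for both), where 4 clock and 2 hypoxia genes fell, and without WT Control 2 there were 4 hypoxia genes that fell. Cytokinin genes changed singly: CKX4 rose by 1.85 ± 0.13, ARR16 by 1.26 ± 0.16 and the expansin EXPA1 fell by 2.06 ± 0.09. The type-A list (2 of 10 rose by either adjustment; adjusted p = 0.356), the breakdown list (4 of 9 rose by either adjustment; 0.119) and the response factors (3 rose and 4 fell of 11 by either adjustment; median 0.10 and mean -0.65, or -0.33 with GATA21, at 0 counts in hy5 Control, held at a floor of 3 counts over the group; 0.48) did not pass. The ACC synthases ACS5, ACS8 and ACS2 rose by 1.73 ± 0.16, 1.32 ± 0.09 and 1.21 ± 0.10. In the ethylene list of 15, 7 rose and 5 fell by either adjustment (adjusted p = 0.0914). The number of calls was 3685 without hy5 Control 1 (1553 lower) and 3430 without it and hy5 BA 2. Higher calls numbered 2026 without hy5 Control 2, and library size only gave 2303 higher and 4263 lower genes.

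With BA in the medium, flavonoid and photosynthesis genes were again lower and jasmonate genes higher in hy5. With an estimated correlation the flavonoid list again passed, and the photosynthesis and jasmonate lists did not (adjusted p = 0.143 each). TT4 was at -5.52 ± 0.43 (adjusted p = 0.0013), FLS1 at -5.22 ± 0.15 and MYB12, a regulator of flavonol synthesis, at -4.75 ± 0.26, and ASN1, an asparagine synthetase, was higher by 2.57 ± 0.09. In all 5321 genes were called, 2505 higher and 2816 lower, of which 430 and 566 changed at least 2-fold. Both media called 1659 genes higher, where independent lists would share 342.7, and 1664 lower, where they would share 321.9, with 18 in opposite directions. The folds had r = 0.72 across genes and share no library. The number of calls was 3366 without hy5 BA 2 (1586 higher and 1780 lower) and 2998 without it and hy5 Control 1, and higher calls numbered 1643 without hy5 BA 1.

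Of 15 flavonoid genes 10 fell (1 higher and 10 lower adjusted over the list alone; adjusted p = 9e-39, and adjusted p = 0.00372 with an estimated correlation). Of 26 light signalling genes 18 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 9.18e-23, and adjusted p = 0.0117 with an estimated correlation). This list again includes HY5 itself. Of 47 photosynthesis genes 35 fell and 1 rose (35 and 3 adjusted over the list alone; adjusted p = 2.26e-34, but adjusted p = 0.143 with an estimated correlation), and 5 rose without hy5 Control 1 or 2. GUN5 was at -2.97 ± 0.11 and PSBR at -2.21 ± 0.08. Of 11 wounding genes 10 rose by either adjustment (adjusted p = 3.96e-21, but adjusted p = 0.143 with an estimated correlation). JAZ10 was at 1.34 ± 0.07. The shoot markers did not pass (2 of 7 rose; adjusted p = 0.536). Of 10 hypoxia genes 9 fell by either adjustment (adjusted p = 9.82e-06, but adjusted p = 0.303 with an estimated correlation). An example was AT4G33070, a pyruvate decarboxylase of ethanol fermentation (-0.86 ± 0.09), and 5 fell without hy5 BA 2. Of 11 response factors and induced genes 7 fell and 2 rose by either adjustment (adjusted p = 0.00016, but adjusted p = 0.114 with an estimated correlation). LBD3 was at -1.26 ± 0.12 and CRF6 at -0.95 ± 0.11, and 3 of the list fell without WT BA 1 and 4 without hy5 BA 2. Of 10 type-A regulators 5 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.42). ARR7 was at -0.64 ± 0.11 and ARR4 at -0.45 ± 0.07. Of 9 root hair genes 6 fell by either adjustment (adjusted p = 0.00156, but adjusted p = 0.395 with an estimated correlation). Examples were the expansins EXPA7 (-1.01 ± 0.12) and EXPA18 (-0.73 ± 0.11).

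**Figure D3:**
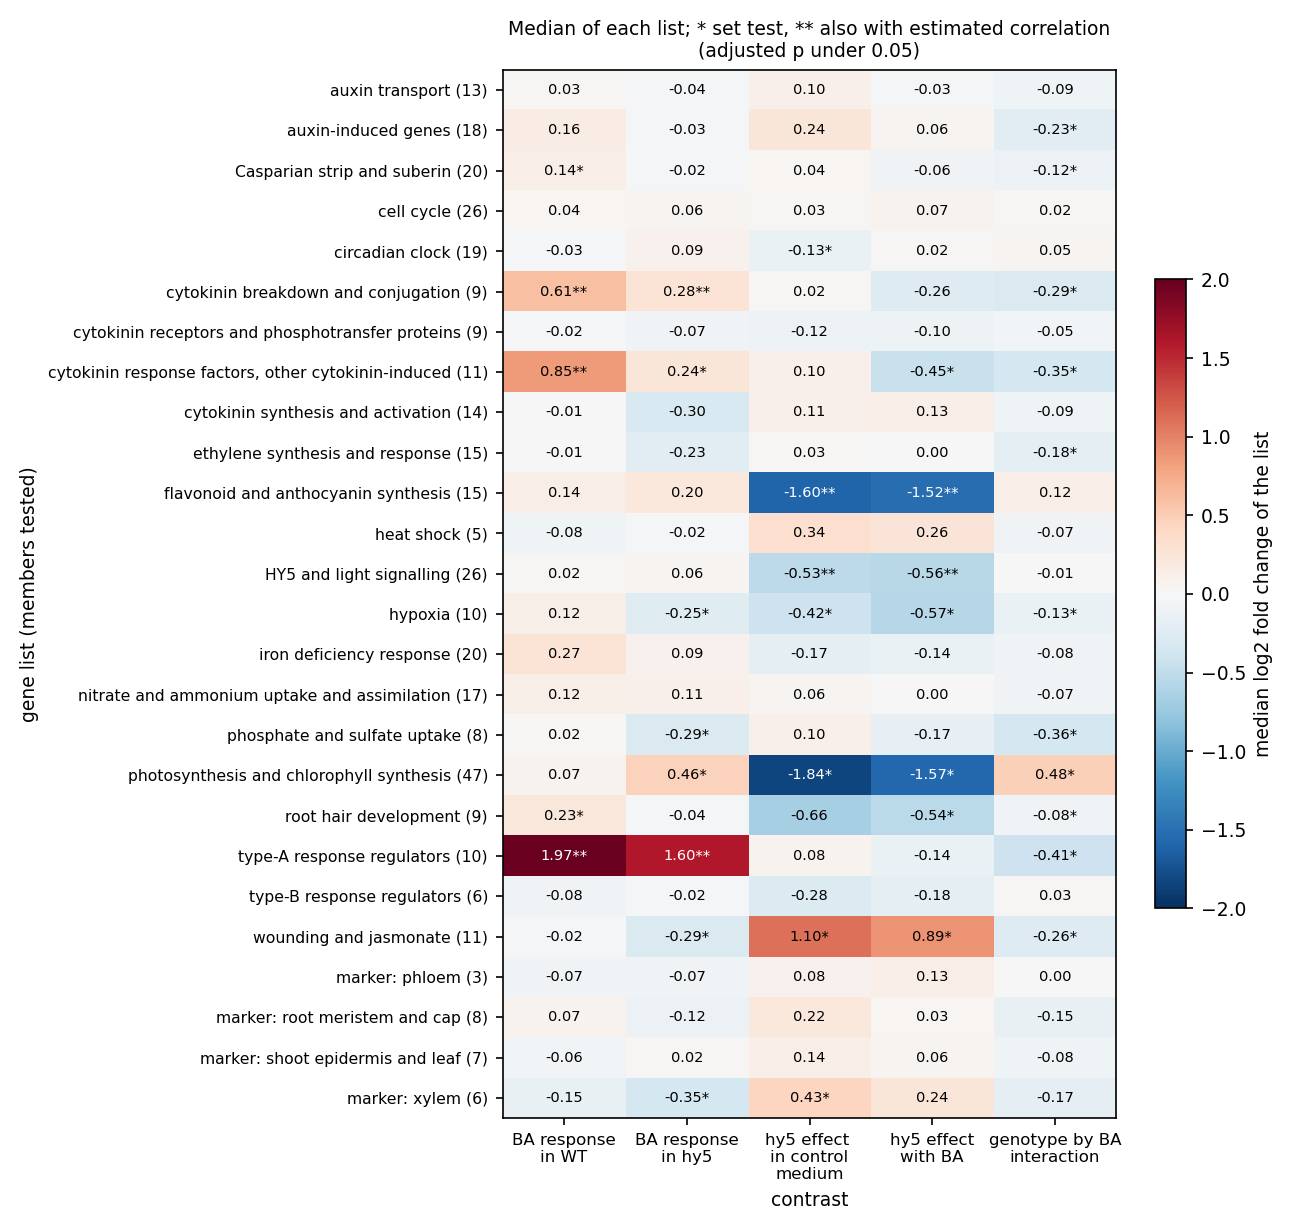
Median log2 fold change of the 26 gene lists (lines) in 5 comparisons (columns), as colour and number; 1 star marks lists that passed camera with the preset correlation and 2 stars those that also passed with an estimated correlation. Type-A regulators stood at 1.97 and 1.60 with BA, and photosynthesis genes at -1.84 and -1.57 in hy5.

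The BA and hy5 effects, each averaged over the other factor, had r = -0.116 (jackknife SE 0.206) and rho = -0.104 over all genes. With 1 library left out, r ran from -0.203 to -0.0174. Both averages use all 8 libraries, and their noise is unrelated only where the 4 groups vary alike. The chi-square per gene between libraries was 3.86 in hy5 Control and 8.24 in WT Control. Among called genes, 835 were lower with BA and higher in hy5, where independent lists would share 403.2, and 372 were higher with BA and lower in hy5 against 246.3. A further 355 were higher in both against 261 and 399 lower in both against 380.5. Within the single comparisons, which share the WT Control libraries, 289 genes were higher with BA in WT and in hy5 Control against 120.3, and 199 were lower in both against 112.3. In opposite directions, 244 were lower with BA and higher in hy5 Control against 134.3, and 127 were higher with BA and lower in hy5 Control against 100.5. Groups simulated without effects called only 4.3 and 3.45 genes on average in these comparisons and shared 0.95. They therefore cannot show how much the shared libraries add to the overlap of real calls. The observed r was 0.193. The simulated r was 0.492, but it comes from noise alone and is not comparable in size. The covariance was 0.042 against 0.023 simulated. BA in hy5 and the hy5 effect in control medium share the hy5 Control libraries instead. In that pair, 899 genes were lower with BA and higher in hy5 Control against 248.6, and 168 the reverse against 80.7. A further 123 were higher in both against 96.6, and 130 lower in both against 207.7. Its r was -0.369 (-0.515 simulated) and its covariance -0.083 against -0.024 simulated. Part of the excess in overlap of either pair may come from the shared libraries.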

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

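The tests of scaling, of shoot tissue and of the level in hy5 Control 1 were chosen only after the results they measure had been seen; the other tests were set earlier.

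A difference between the genotypes in the response to BA was tested directly, as an interaction in edgeR, and 110 genes passed. Those named by rule with a more negative response in hy5 were AAE12 (-1.55), AT3G22250 (-1.43), AT2G30540 (-1.25), RSL4 (-1.19), ACS5 (-1.15), AT4G22620 (-1.14), ST4B (-0.73), AT3G13610 (-0.71), ACS8 (-0.62), AT4G33070 (-0.61) and ARR4 (-0.59). Those with a more positive response were AHA10 (1.28), ATPC1 (1.24), ATCG00680 (1.17), AT3G47675 (1.09), ATCG00020 (0.98) and IMPA-8 (0.97). Of these 17 genes, AT4G22620 alone was called in each run that left out 1 library, though not without hy5 Control 1 and hy5 BA 2 together (adjusted p = 0.0869), and AT3G47675 and AT3G13610 overlap another gene in position.

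Gene lists also differed between genotypes by the same test with camera's preset correlation, with adjusted p-values of 1.1e-08 for photosynthesis, 0.000264 for cytokinin response factors and induced genes, 3e-04 for type-A regulators and also 3e-04 for wounding and jasmonate, 0.00301 for phosphate and sulfate uptake and 0.0155 for ethylene. The values were 0.0235 for auxin-induced genes, 0.0235 for cytokinin breakdown, 0.049 for root hairs, 0.0493 for Casparian strip and suberin and 0.0493 for hypoxia. With an estimated correlation the adjusted p of these 11 lists ran from 0.307 to 0.625. With 1 library left out, 6 of them lost their call in some runs. Casparian strip and suberin was lost without WT Control 2 (0.575), WT BA 2 (0.316), hy5 Control 1 (0.249), hy5 BA 1 (0.0791) and hy5 BA 2 (0.0719). Root hairs were lost without WT Control 2 (0.25), WT BA 2 (0.503), hy5 Control 1 (0.15) and hy5 BA 1 (0.0573), and auxin-induced genes without these 4 in turn (0.0685, 0.0723, 0.113 and 0.0589). Hypoxia was lost without WT Control 1 (0.178), WT BA 1 (0.189), hy5 Control 2 (0.443) and hy5 BA 2 (0.241). Ethylene was lost without WT BA 1 (0.0594), hy5 Control 2 (0.0569) and hy5 BA 2 (0.0962), and cytokinin breakdown without WT BA 1 (0.0989) and hy5 BA 1 (0.0747).

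Most of the interaction terms were negative, 99 of 110. The share of negative calls was 92% with RLE scaling but 60% with library size only. Among the 500 genes with the smallest p it was 79.4% with TMM, 81.2% with RLE and 35.8% with library size only. Library size only moved the median interaction of all genes by 0.106 and RLE by -0.0071, so the change of share with the former comes with a shift common to all genes. No value here shows which scaling is right, so the scaling of libraries as a cause cannot be told apart from a real difference between genotypes. Without hy5 Control 2, 47.8% of the 23 calls were negative, and among the 500 genes with the smallest p the share fell to 62.2%, between the values set for and against a single library as the cause, which therefore stays open too. A hypothesis from the design is that BA may move genes changed by the mutation back toward their WT level: the median interaction was -0.089 (jackknife SE 0.067) for genes raised in hy5 and -0.027 (SE 0.069) for genes lowered in hy5, neither clear of 0 by more than about its error. With library size only these medians were 0 and 0.082, so it also stays open.

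Photosynthesis genes were lower in hy5, with a list median of -1.65 for the effect averaged over treatments. If shoot tissue left in the WT samples were the cause, leaf genes at low level in roots should be lower in hy5 too. The mean of RBCS1B, RBCS2B and RBCS3B was fitted at 3.33, though RBCS3B was not called (adjusted p = 0.459). RBCS1B was at 0 counts in WT Control, so its fitted fold is not exact and neither is this mean. The fold of RBCS1B in control medium was 5.62 as fitted and 2.00 with WT Control held at a floor of 3 counts over the group. These genes were near 0, and summed to between 0.673 and 1.61 CPM in WT, 0.0306 CPM in hy5 Control 1 and between 3.26 and 7.23 CPM in the other hy5 libraries. The 7 shoot markers summed to between 73.3 and 81.9 CPM in WT and between 79.6 and 87.7 CPM in hy5. They were thus not higher in WT, as shoot tissue there would make them, but how much tissue would move them was not tested. RBCS1A went the other way from RBCS1B, RBCS2B and RBCS3B. Shoot tissue therefore cannot be told apart from an effect of the genotype, which remains an untested possibility. The rise of the list with BA in hy5 may rest in part on a low level in hy5 Control 1, since its median was 0.46 (jackknife SE 0.42 over libraries) with that library and 0.30 without it. It was 0.64 without hy5 BA 1 and 0.40 without hy5 BA 2. Lost calls do not point to hy5 Control 1 alone, since PSBR lost its call without hy5 BA 1 as well. The median without hy5 Control 2 was 0.85, so the spread between libraries is too wide to decide, and this stays open.

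Genes with the largest hy5 effects could lie in a chromosome segment carried over from another accession. Of 240 such genes placed in 106 windows of 1 Mb, the highest share was 4% in a window of chromosome 5. Of 10000 shuffles of positions, 24.99% gave a window at least as high (median 3.51%). This argues against 1 segment that gathers most of these genes. A smaller segment was not tested, nor was the window that holds HY5 on its own. Differences spread over all chromosomes, as in a mutant of another accession, would not show in this test.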

How the results depend on the processing

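The runs without both hy5 libraries whose counts lay near whole numbers, and the tests of lists with library size only, were chosen after seeing the data. Of 8106 alternative values of named genes, 7197 kept their direction and side of the threshold, 897 no longer passed, 12 newly passed and 0 reversed. Of the losses, 84 came with an adjusted p under 0.01 and 204 with a fold of at least 2. Both thresholds use the main fit, where no direction can change. Most named genes were also chosen for a large fold or small p in these data, which makes reversals unlikely. Where a count below moved by more than 1.5 times, the cause was not tested, except that stricter thresholds leave fewer calls by construction. With 2 libraries per group at this depth, 1.5-fold interactions were recovered in 37.3% of simulated genes, so small differences between genotypes could be missed. The replicate numbers did not pair the libraries (correlations of deviations from -0.184 to -0.004), and with a replicate block 1635, 2281, 5300, 4968, 101 and 3346 genes were called for BA in WT, BA in hy5, hy5 in control medium, hy5 with BA, the interaction and averaged BA.

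At an adjusted p under 0.05 and at least 2-fold there were 220 calls for BA in WT (186 higher, 34 lower), 240 for BA in hy5 (140, 100), 1197 for hy5 in control medium (591, 606), 996 for hy5 with BA (430, 566), 16 for the interaction (4, 12) and 219 for averaged BA (171, 48). At an adjusted p under 0.01 there were 803 (458, 345), 1353 (310, 1043), 3659 (lower 1566), 3313 (1475, 1838), 3 (0, 3) and 2085 (692, 1393) in the same order. Without both hy5 libraries near whole numbers there were 585 for BA in hy5 (167, 418), 3430 for hy5 in control medium (lower 1351), 2998 for hy5 with BA (1392, 1606), 6 for the interaction (3, 3) and 2060 for averaged BA (689, 1371). With library size only, 1712 genes were higher for BA in hy5, 4263 lower for hy5 in control medium, 55 called for the interaction (22, 33) and 2219 higher for averaged BA; the share of rising genes that changed more in WT was 41.9% and their median interaction 0.0391, both reversed. DESeq2 called 416 higher for BA in hy5, 299 for the interaction (21, 278) and 903 higher for averaged BA, and the 4 libraries alone gave 1157 higher for BA in hy5. The interaction had 38 calls with limma-voom (2, 36), 48 without the robust step (4, 44), 72 without organelle genes (3 higher), 6 higher with RLE and 21 higher with no filter.

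Leaving out 1 library at a time gave 841 to 2220 calls for BA in WT (higher 513 to 945, lower 320 to 1275), 1088 to 2867 for BA in hy5 (281 to 846, 772 to 2126), 3685 to 5860 for hy5 in control medium (2026 to 3167, 1553 to 2693), 3366 to 5658 for hy5 with BA (1586 to 2706, 1780 to 3013), 6 to 331 for the interaction (0 to 36, 4 to 309) and 2400 to 4272 for averaged BA (higher 839 to 1623). The median interaction of rising genes lay between -0.183 and -0.0966. With an estimated correlation 3 of 5 gene lists passed for BA in WT, 2 of 7 for BA in hy5, 2 of 6 for hy5 in control medium, 2 of 7 for hy5 with BA and 0 of 11 for the interaction, and 0 marker lists for BA in hy5 and 0 for hy5 in control medium. Of 31 counts above 1 of called members in lists that passed, 13 moved by more than 1.5 times without 1 library, and 48 of 70 in lists that did not pass. Leaving out 1 library gave 3 to 7 gene lists for BA in WT and 7 to 11 for the interaction, and 0 to 1 marker lists for BA in WT, hy5 in control medium and the interaction. The HY5 fold in control medium was -5.34 for its first transcript and -1.85 for its second. The second had 10.2 and 14.6 estimated counts in WT Control and 6.9 and 0 in hy5 Control, so its fold rests on few counts in 1 hy5 library.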

Other observations

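The test of splits within genotypes was chosen only after the count of the 35 splits had been seen; the other tests were set earlier.

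In control medium some members of further lists were called singly for the hy5 effect, while these lists did not pass. Of 18 auxin-induced genes 8 rose and 2 fell by either adjustment (camera adjusted p = 0.101), and LBD16, which acts in lateral root initiation, rose (edgeR adjusted p = 4.97e-06, n = 2 per group). Of 9 root hair genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; adjusted p = 0.119), with the regulator RSL4 at 1.06 ± 0.13 and the wall protein genes LRX1 and PRP3 at -1.01 ± 0.13 and -0.91 ± 0.10. Of 17 nitrate and ammonium genes 2 rose and 4 fell (4 and 4 adjusted over the list alone; median 0.06 and mean -0.03, adjusted p = 0.75). The ammonium transporter AMT1;2 was at 0.78 ± 0.12 and LBD39, a repressor of nitrate-responsive genes, at -1.17 ± 0.12. Of 5 heat shock genes 4 rose (5 adjusted over the list alone; adjusted p = 0.0605), such as HSFA2 at 0.34 ± 0.07.

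The 8 libraries can be divided into 4 and 4 in 35 ways, and a fit with 1 term was run on each. The genotype split called 4945 genes and the highest other split 465, so 1 of 35 splits reached the real count. That is the smallest share these splits can give. In every other split the genotype difference adds to the spread of a fit with 1 term, which lowers its calls. This count therefore does not by itself exclude chance for the hy5 effect. The BA split called 465 genes and the genotype split 4945, so 2 of 35 splits reached it and this count does not by itself exclude chance for the BA response. The genotype split follows the structure of the samples, and its larger effect kept the share above 5%; the other 33 splits called 0 genes. With genotype in the model, the BA split called 2824 genes and the highest other of the 18 splits that divide each genotype evenly called 0, with 1 of 18 reaching the real count, too few splits for a share under 5%. These counts do not bear on single lists. By camera with an estimated correlation the type-A regulators passed in WT (adjusted p = 0.00187) and in hy5 (0.00452). The responses in WT and hy5 share no library. Both tests use 1 fit over all 8 libraries and its estimate of the spread, so they are not independent.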
